A study of Drosophila melanogaster and Homo sapiens with 32 samples.

How the data were processed

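RNA of Drosophila DL1 cells was selected with oligo-dT and sequenced from 3 control libraries and 3 libraries labelled IntS8-depleted, and the series text calls these replicate sets biological. Per the submitters' processing notes, cutadapt 1.14, STAR and Bowtie 1.2.2 and the builds hg38 and dm3 were used in the series, with no role given, and the counting tool, its use of strand and the annotation are not given in the sources used here. Reads of overlapping or antisense genes and of near-identical copies may therefore be split or shared in ways that cannot be seen here.

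Per the file headers, the authors deposited for each transcription start a signal for each group, the mean normalized count over its libraries. Per the file headers, the authors also deposited the log2 fold change of the IntS8-depleted over the control group with its standard error. The p-value and adjusted p, a class of expression change and a mark for changed splicing are likewise given per the file headers by the authors. The deposited p-value equals, within 0.001 for 100% of genes, that of a normal law on the fold change over its standard error. The table had 10668 rows for 8574 genes. All rows of a gene held the same values (0 genes differed), so each gene was used once. A symbol was found for 8378 of the genes, from a table that pairs gene IDs with names. Gene spans, and which genes neighbour each other, came from the RefSeq table of Release 6 plus ISO1 MT, and no coordinate of it is printed. There were 0 unused columns of per-sample values.

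Because the table holds the comparison and no value per library, the deposited test was used, and a gene was called at a deposited adjusted p under 0.05. An adjusted p that the authors left as NA stayed NA. The authors' classes of up- and downregulated genes held 967 genes, all of them past adjusted p 0.0001 and 1.5-fold, and none marked as changed in splicing. Fold changes carry the standard errors of the authors' deposited table, and no spread or replicate number was computed here.

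Whole reads could be recovered for low genes. A group mean is the sum over 3 libraries of a read count times the worth of 1 read in that library, and the 3 smallest means of a group give these worths. Of 1896 control and 1850 depleted-group means above 0 and under 100, all were matched by exactly 1 combination of whole reads within 5e-08, and on 389 simulated means all were recovered. The simulated means were built from the same worths that decoded them, so they do not test whether those worths were right. Of 100 higher means drawn between 400 and 600, exactly 1 combination was found for 100 in the depleted group and for 77 in the control group, against any match for 53 and 68 of as many means shifted off the steps, so that a match alone is weak evidence at such means, the control group was resolved in part only, and no count test was run on recovered reads. The libraries carry no label in this recovery and were not tied to replicate numbers, and totals of reads per library are unknown. For a gene with 0 reads in a group, a floor of 3 reads over the group was used (a mean normalized count of 0.785 in the control group and 0.874 in the other). For 1 to 3 reads the ratio is given with an exact binomial 95% interval. Floors and intervals cover counting error only. Reads at low genes were clumped: of the genes with 8 to 15 reads, 91 of 160 in the control group and 85 of 134 in the other had all of them in 1 library.

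Gene lists, 34 in all, were fixed before the data were examined. The list test was cameraPR of limma 3.58.1 in R 4.3.3 on the fold change over its standard error, with an inter-gene correlation of 0.01, two-sided, over 7264 genes with a mean of the group means of at least 10. Lists needed 5 tested members, and Benjamini-Hochberg adjustment ran over the 31 lists tested. A test with an estimated correlation needs values per library and was not possible, so which calls hold with one is unknown. On simulated statistics of the same 7264 genes, drawn independently, the 6 shifted lists were called and 0 of the others. That checks the running of the test only, and cannot show how often correlated genes give a false call. List medians were the same to 2 decimals with genes of an empty control group set at their bound.

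Named genes followed a rule fixed before the data were examined. It takes IntS8, the 12 highest and 12 lowest called genes with a mean of at least 100, up to 4 called members and 1 unchanged member of each list with a list call or at least 3 called members, every measured Integrator subunit, and the PP2A subunits mts, Pp2A-29B, tws, wdb and wrd. Genes known by a CG number alone were counted and not named. The text names a subset of the genes the rule gives, picked after their values were seen. Alternatives were other thresholds, adjustments and filters, centring on all genes or on ribosomal proteins, a rank version, Fisher's exact test, a background mean of at least 100 and 10000 random lists matched on mean expression. Fisher's exact test and the random lists allow for no correlation between genes. Other software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.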

Results

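The series asks how IntS8, a subunit of the Integrator complex, and the phosphatase PP2A act on paused RNA polymerase II. Integrator is a metazoan complex that cleaves nascent transcripts, among them the precursors of spliceosomal snRNAs. The data at hand were from RNA sequencing of oligo-dT selected RNA of DL1 cells, a Drosophila melanogaster line that the labels trace to late embryos. There were 3 control libraries, from cells given dsRNA against β-galactosidase for 60 hours, and 3 libraries labelled IntS8-depleted, from cells given dsRNA against IntS8 for 60 hours. The remaining 26 samples of the series were not analysed here. The authors' deposited table gave 1 mean normalized count per gene and group, so that the error of each comparison was the standard error of the log2 fold change in that table. Mean normalized counts summed to 11630300 in the control group and 12029000 in the other. The relative depths of the control libraries, recovered from the steps between low group means, were 1.42, 1.24 and 1.19, and those of the libraries labelled IntS8-depleted were 1.44, 1.10 and 0.983.

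IntS8 itself was not detectably lower in the authors' deposited table. The row taken for IntS8 (FBgn0025830, dm3 chromosome 2R, plus strand, transcription start 12737989) had no symbol in the name table used. It was identified by its place between mir-8 and Fen1 and its deposited length of 3246 nt, which of the 4 genes between that pair in the Release 6 plus ISO1 MT annotation only IntS8 is long enough to hold. Its mean normalized count in the authors' deposited table was 534 in the control group and 486 in the group labelled IntS8-depleted. The log2 fold change was -0.14 ± 0.72 (SE, the authors' deposited table), with adjusted p = 0.915, and a 95% interval of 0.343 to 2.41 for the ratio. That standard error was exceeded by 14 of the 1858 genes with a mean normalized count between 300 and 900, whose median standard error was 0.23. The recovered reads behind the mean of 486 were uneven, with normalized values of 706, 47.2 and 705 across the libraries labelled IntS8-depleted. A match of whole reads is weak evidence at such means. The target thus does not check the labels, and each direction below is from the libraries labelled IntS8-depleted against the control libraries.

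Of 8574 genes, 1603 were higher and 873 were lower in the libraries labelled IntS8-depleted at the adjusted p of the authors' deposited table, 5254 did not pass, and 844 had no adjusted p. The increases were the larger changes: 705 of the genes that rose did so by more than 4-fold, against 27 of the genes that fell. Among the genes with a mean of at least 100, those furthest up included rk, which encodes the bursicon receptor, Nep1, a neprilysin-type peptidase, amon, a prohormone convertase, tok, a tolloid-like protease, and Tsp, which encodes thrombospondin. No read of these genes was present in the control libraries of the authors' deposited table. Their mean normalized counts in the libraries labelled IntS8-depleted were 1038 for rk, 661 for Nep1, 509 for amon, 454 for tok and 416 for Tsp. Against a floor of 3 reads over the control group, rk was at least 1323-fold higher and Tsp at least 530-fold higher in the authors' deposited table. Dtg and t, at 312 and 282 against no control read in that table, were also among the 12 with the largest increase at that mean.

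Among genes with a mean of at least 100, the lowest log2 fold change in the authors' deposited table was that of Ids, and 6 lower genes at any mean changed by more than 16-fold. Ids, which encodes a lysosomal sulfatase, fell by 2.26 ± 0.48 (SE) on the log2 scale, from 247 to 51.9. SmD3, a core protein of the spliceosomal snRNPs, fell by 1.94 ± 0.27 on the same scale, from 565 to 147 in the authors' deposited table. The log2 fold changes of the authors' deposited table were -1.86 ± 0.54 for Rim, -1.81 ± 0.37 for GILT3 and -1.71 ± 0.26 for tow. The cleavage stimulation factor gene CstF50 was at -1.64 ± 0.34 and the metallothionein gene MtnA at -1.57 ± 0.34 on that scale in the authors' deposited table. The plot of group means shows both tails.

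**Figure D1:**
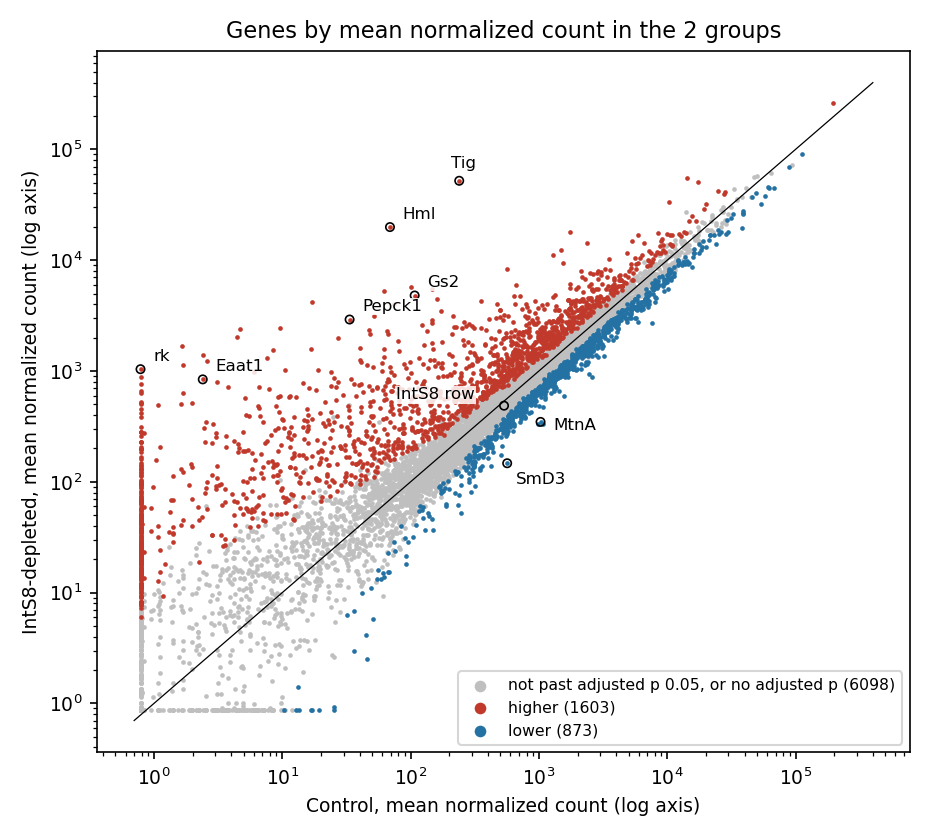
Mean normalized count of each gene in the control group (x) and in the group labelled IntS8-depleted (y), both on log axes, from the authors' deposited table. Each point is a gene, values under the floor of 3 reads are drawn at the floor, and the line marks equal values. Red points are the 1603 higher and blue points the 873 lower genes, and Hml and Tig lie far above the line.

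The split of the calls depended on the scaling of the authors' deposited table. The 79 tested cytosolic ribosomal protein genes had a median log2 fold change of -0.34, and centring the fold changes on that median raised every gene by 0.34. With that scaling 2543 genes were higher and 198 lower, or 92.8% higher in place of 64.7%. Of the genes named below, IntS12, mts, wrd, Cka, ATPsynO, ND-B17, RpL9, Prosalpha5, Prosalpha7, Fcp1, Dis3, Cpsf6 and 14-3-3epsilon then no longer passed as lower. With it zfh1, LanB1, Gapdh2, stg, Rpn1, Ssrp and eEF2 passed as higher. With a stricter limit of adjusted p under 0.0001 and 1.5-fold, 909 genes were higher and 155 lower in the authors' deposited table.

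Of the 31 gene lists with at least 5 tested members, 10 were higher and 6 lower than the other genes by the list test. Hemocyte markers rose in the authors' deposited table: of 21 tested, 14 were higher, 0 lower and 7 did not pass, and 16 were higher when adjusted over the list alone (list test adjusted p = 2.43e-13). The rank version of the list test, in which single genes weigh less, also passed (adjusted p = 2.86e-06). Hml, the clotting protein hemolectin, went from 69.0 to 19891 in the authors' deposited table, a log2 fold change of 8.18 ± 0.23 (SE). The phagocytic receptor gene NimC1, from a low control mean of 5.59 to 109, rose by 4.24 ± 0.57 and the collagen IV gene vkg by 3.98 ± 0.26 on the log2 scale of the authors' deposited table. The transcription factor gene gcm, with 2 control reads, had a ratio of 95.4 with a counting interval of 23.3 to 715 in the authors' deposited table. The transcription factor gene zfh1, at 11452 and 13860 in the authors' deposited table, did not pass (log2 fold change 0.28 ± 0.22). In the control libraries 13 of the 21 hemocyte markers already had a mean of at least 100, as did 19 of the 25 matrix genes, 7 of the 10 glial, 5 of the 10 neuronal, 3 of the 6 fat body and 12 of the 14 epithelial markers. Of the hemocyte markers 6 belong to another list as well.

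Genes for extracellular matrix and integrins were higher in the same direction in the authors' deposited table, 17 of 25 tested with 0 lower, and 18 when adjusted over the list alone (list test adjusted p = 1.56e-19). By the rank version of the list test this was adjusted p = 2.95e-05. Tig, which encodes the integrin ligand tiggrin, went from 239 to 52046, a log2 fold change of 7.77 ± 0.12 (SE) in the authors' deposited table. The integrin alpha gene if, from a low control mean of 1.97 to 517, rose by 8.13 ± 0.66 and the laminin alpha gene wb by 5.33 ± 0.34 on the log2 scale of the authors' deposited table. Timp, an inhibitor of metalloproteinases, had no control read and was at least 260-fold higher in the authors' deposited table. LanB1, the laminin beta chain, was at 7405 and 7737 in the authors' deposited table and did not pass.

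Markers of other cell types moved with the libraries labelled IntS8-depleted too. Glial markers were higher for 8 of 10 and lower for 1 of 10 in the authors' deposited table (8 and 1 adjusted over the list alone; list test adjusted p = 1.06e-06). The glutamine synthetase gene Gs2 went from 107 to 4798, the glutamate transporter gene Eaat1 from 2.40 to 840, and the glial transcription factor gene repo from 28.0 to 211 in the authors' deposited table. Their log2 fold changes were 5.49 ± 0.19, 8.35 ± 0.55 and 2.91 ± 0.39 (SE, the authors' deposited table). Of the glial markers 3 belong to another list as well, among them Eaat1, which also counts as 1 of the 6 higher neuronal markers. Fat body markers were higher for 5 of 6 with 0 lower in the authors' deposited table (5 adjusted over the list alone; adjusted p = 1.14e-05), among them regucalcin (5.75 ± 0.27), the lipoprotein gene Apoltp (4.92 ± 0.33) and the lipid transfer gene Mtp (1.90 ± 0.23). Neuronal markers were higher for 6 of 10 with 0 lower in the authors' deposited table (6 adjusted over the list alone, list test adjusted p = 0.00385), among them nrv3 (4.72 ± 0.79, from a low control mean of 6.79 to 177) and the microtubule-associated gene futsch (4.42 ± 0.38). Epithelial and cuticle markers were higher for 7 of 14 with 0 lower in the authors' deposited table (8 adjusted over the list alone; adjusted p = 0.0140), including the adhesion gene Fas3 (1.74 ± 0.20) and the polarity gene crb, which went from 976 to 2760. Muscle markers, with 3 of 7 higher in the authors' deposited table, did not pass the list test (adjusted p = 0.193), nor did germline and piRNA genes, with 1 of 14 higher and 3 lower (adjusted p = 0.164). The calls of the neuronal and the epithelial list were lost once gene span and expression were taken out of the statistic, with adjusted p = 0.145 and adjusted p = 0.110. With the rank version of the list test the glial list was at adjusted p = 0.00331 and the fat body list at adjusted p = 0.0110.

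Metabolic and immune groups rose as well. Glutathione transferases and cytochrome P450s were higher for 28 of 50 and lower for 1 in the authors' deposited table, with the same counts adjusted over the list alone (list test adjusted p = 0.000782). GstE3 rose by 3.70 ± 0.38 on the log2 scale of the authors' deposited table, Cyp49a1 was at least 59.9-fold higher than the floor of its empty control, and GstD3 (0.16 ± 0.21) did not pass. In glycolysis and gluconeogenesis 9 of 18 were higher and 1 lower in the authors' deposited table, as they were adjusted over the list alone (list test adjusted p = 0.000272). The genes higher in the authors' deposited table included gluconeogenic and trehalose enzymes, with Pepck1 at 6.45 ± 0.27, fbp at 4.15 ± 0.39 and Treh at 2.19 ± 0.17 (log2, SE). Gapdh2 of glycolysis, at 0.19 ± 0.17 in the authors' deposited table, did not pass. Antimicrobial and humoral immune genes were higher for 7 of 12 with 0 lower in the authors' deposited table, 9 when adjusted over the list alone (list test adjusted p = 0.0306), with the Toll ligand gene spz at 1.76 ± 0.16 and the receptor gene PGRP-SA at 1.67 ± 0.36. That list lost its call once span and expression were removed (adjusted p = 0.0655). JAK-STAT and thioester-protein genes were higher for 6 of 10 and lower for 1 in the authors' deposited table, also when adjusted over the list alone (list test adjusted p = 0.00439), with Tep1 at 3.19 ± 0.20, Tep2 at 2.12 ± 0.22 and et at 2.96 ± 0.42.

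**Figure D2:**
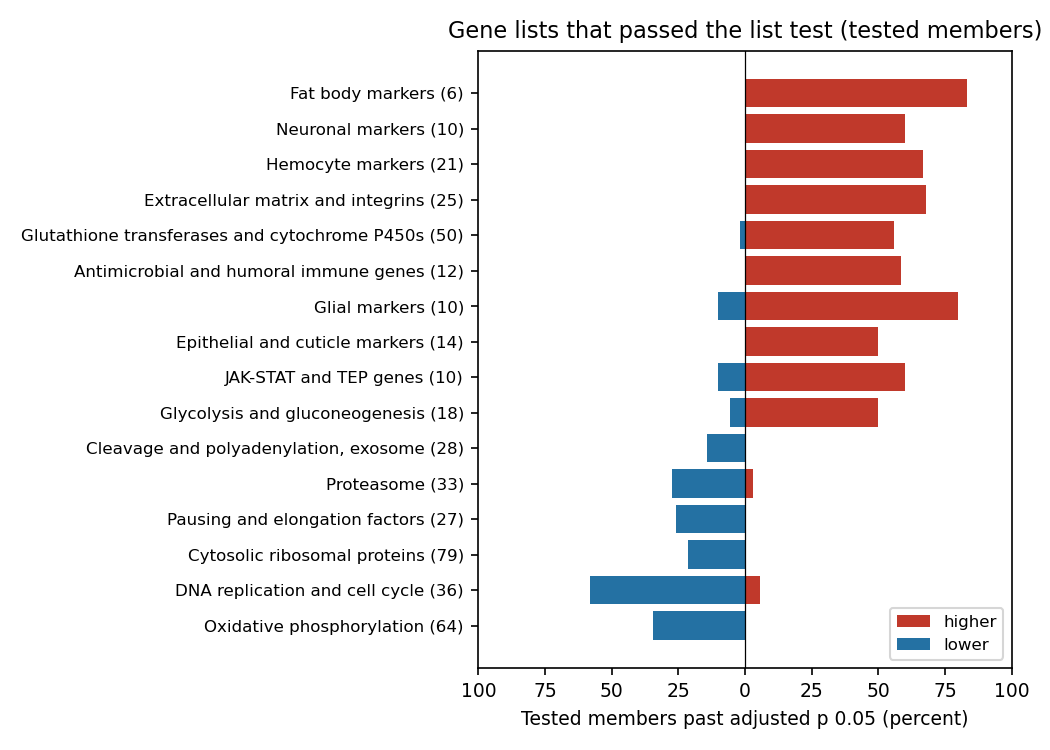
Share of each list's tested members (number in brackets) that were higher (red, to the right) or lower (blue, to the left) at adjusted p under 0.05 in the authors' deposited table, in percent, for the 16 lists that passed the list test. Hemocyte and matrix lists had 14 of 21 and 17 of 25 members higher, and the cell cycle list had 21 of 36 lower.

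Genes of DNA replication and the cell cycle fell: 21 of 36 were lower and 2 higher in the authors' deposited table, 22 and 2 when adjusted over the list alone (list test adjusted p = 0.000440). The log2 fold changes of the authors' deposited table were -1.23 ± 0.28 for the kinase gene Cdk1, -1.12 ± 0.16 for CycE and -1.03 ± 0.26 for the origin recognition gene Orc2. RnrS, the small subunit of ribonucleotide reductase, rose by 1.27 ± 0.15 in the authors' deposited table, and stg, the Cdc25 phosphatase, at 0.26 ± 0.13, did not pass. Genes of oxidative phosphorylation fell for 22 of 64 with 0 higher in the authors' deposited table, also when adjusted over the list alone, at a median log2 fold change of -0.54 (list test adjusted p = 7.03e-05). ATPsynO was at -1.07 ± 0.42 and the complex I gene ND-B17 at -1.02 ± 0.30 on the log2 scale of the authors' deposited table, while ATPsynbeta (-0.14 ± 0.11) did not pass. Cytosolic ribosomal protein genes were lower for 17 of 79 with 0 higher in the authors' deposited table, 16 adjusted over the list alone (list test adjusted p = 9.95e-05), with RpS13 at -0.76 ± 0.16, RpL9 at -0.60 ± 0.19 and RpS6, which did not pass, at -0.16 ± 0.17. Proteasome genes were lower for 9 of 33 and higher for 1 in the authors' deposited table, with the same counts adjusted over the list alone (list test adjusted p = 0.00439), with Prosalpha5 at -0.81 ± 0.21, Prosalpha7 at -0.70 ± 0.22 and Rpn1, which did not pass, at 0.14 ± 0.11. Removal of span and expression ended the calls of the ribosomal (adjusted p = 0.160) and proteasome lists (adjusted p = 0.257), and Fisher's exact test of the lower calls passed for neither (adjusted p = 0.105 for each). That of the higher calls passed for both, as fewer members were higher than among the other genes (adjusted p = 3.65e-07 and adjusted p = 0.0174). On the ribosomal protein scaling the median was 0.00 by construction for the ribosomal list, 0.07 for the proteasome, -0.21 for oxidative phosphorylation and -0.10 for the cell cycle. With it 7 cell cycle genes were higher and 5 lower. Oxidative phosphorylation then had 0 higher and 7 lower, the proteasome 3 and 0, and the ribosomal list 1 and 1.

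Among factors of the transcription machinery, pausing and elongation factors were lower for 7 of 27 with 0 higher in the authors' deposited table and when adjusted over the list alone (list test adjusted p = 0.0122). Spt6, an elongation factor, was at -0.58 ± 0.10 and the polymerase CTD phosphatase gene Fcp1 at -0.56 ± 0.16 on the log2 scale of the authors' deposited table, and Ssrp (0.07 ± 0.13) did not pass. Cleavage, polyadenylation and exosome genes were lower for 4 of 28 with 0 higher in the authors' deposited table and adjusted over the list alone (list test adjusted p = 0.0194), namely CstF50, the nuclear exosome helicase gene Mtr4 (from 1312 to 655), the exosome nuclease gene Dis3 (-0.63 ± 0.18) and Cpsf6 (-0.33 ± 0.12). On the ribosomal protein scaling both medians turned, to 0.05 for the first list (4 genes higher, 2 lower) and 0.09 for the second (1 higher, 2 lower). Both calls were lost once span and expression were removed (adjusted p = 0.0734 and adjusted p = 0.0891). Fisher's exact test of the lower calls passed for neither (adjusted p = 0.181 and adjusted p = 0.883). That of the higher calls passed for both, as fewer members were higher than among the other genes (adjusted p = 0.0111 and adjusted p = 0.00791). The first list was at adjusted p = 0.0579 on the ribosomal protein scaling, and the second at adjusted p = 0.0669 against 10000 random lists. Of 11 tested RNA polymerase II subunits 1 was lower in the authors' deposited table and the list did not pass (adjusted p = 0.235).

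The other measured Integrator subunits did not move together. By the authors' deposited table, of 13 there were 3 higher, 1 lower and 9 that did not pass, with the same counts adjusted over the list alone (list test adjusted p = 0.572). omd rose by 0.94 ± 0.23, IntS2 by 0.76 ± 0.17 and IntS6 by 0.70 ± 0.18 on the log2 scale of the authors' deposited table, and IntS12 fell by 0.75 ± 0.27. IntS2 and IntS6 lie on the X chromosome, as does IntS4, which did not pass at 0.02 ± 0.32. X-linked genes with a mean of at least 100 had a median log2 fold change of 0.18 against -0.08 for the autosomes in the authors' deposited table. The 9 others, IntS1, IntS3, IntS4, IntS9, IntS10, IntS11, IntS14, defl and asun, ranged from -0.82 to 0.38 in log2 fold change in the authors' deposited table. Of the PP2A subunits, the catalytic gene mts was lower at -0.56 ± 0.11 and the regulatory gene wrd at -0.37 ± 0.15 on the log2 scale of the authors' deposited table. The scaffold gene Pp2A-29B (-0.22 ± 0.14) and the regulatory genes tws (-0.20 ± 0.20) and wdb (-0.04 ± 0.18) did not pass in the authors' deposited table. Over the list of PP2A and related phosphatases 4 of 15 were lower, with Cka at -0.48 ± 0.15, and 1 was higher, flw at 0.54 ± 0.17, in the authors' deposited table (the same counts adjusted over the list alone; list test adjusted p = 0.120).

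The authors' deposited table listed 13 RNA polymerase II snRNA genes, some with no read in either group, of which 3 were higher and 0 lower, too few at sufficient level for a list test. snRNA:U4:39B went from 1.97 to 137, a log2 fold change of 6.22 ± 0.61 (SE, the authors' deposited table). snRNA:U5:63BC, at 11.0, and snRNA:U1:82Eb, at 6.00 and at least 7.64-fold higher, had no control read in the authors' deposited table. Both lost the call at adjusted p under 0.01. The RNA was oligo-dT selected, so these counts are of RNA captured that way and do not measure total snRNA levels. Of the RNA polymerase III small RNA genes, 3 were in the authors' deposited table and 0 passed, and the table held 0 replication-dependent histone genes.

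In the remaining lists members passed singly, and none of these lists passed the list test. Ecdysone response genes were higher for 8 of 17 with 0 lower in the authors' deposited table (adjusted p = 0.0784), among them the nuclear receptor genes Hr3 (5.00 ± 0.53) and Hr4 (4.24 ± 0.45). Immediate-early, EGFR and JNK pathway genes were higher for 13 of 29 and lower for 4 in the authors' deposited table (adjusted p = 0.0660), with the protease gene Mmp2 at 4.10 ± 0.27, the cytokine gene upd2 at 4.07 ± 0.71 and Hr38 at 3.30 ± 0.43. Adjusted over the list alone, 8 ecdysone genes and 15 immediate-early genes were higher. Both lists passed with the rank version of the list test (adjusted p = 0.0120 and adjusted p = 0.0249), and also with Fisher's exact test and on the ribosomal protein scaling. The immediate-early list passed against 10000 random lists as well (adjusted p = 0.00124). Notch targets were higher for 6 of 12 with 0 lower in the authors' deposited table (7 adjusted over the list alone, list test adjusted p = 0.188), with fng at 4.63 ± 0.78, from a low control mean of 3.57 to 86.7. The Notch list passed with Fisher's exact test (adjusted p = 0.0403) and against random lists (adjusted p = 0.0335). Both of these alternatives treat genes as independent, which the list test does not, so such passes are weaker evidence for genes regulated together. Metal response genes were higher for 6 of 13 and lower for 1, MtnA, in the authors' deposited table (the same adjusted over the list alone; adjusted p = 0.199), among them the ferritin gene Fer2LCH at 0.68 ± 0.11. Heat shock genes and chaperones were higher for 5 of 14 and lower for 4 in the authors' deposited table (5 and 5 adjusted over the list alone; adjusted p = 0.109, but adjusted p = 0.00809 with span and expression removed and adjusted p = 0.0278 on the ribosomal protein scaling), with the small heat shock genes Hsp23 at 2.53 ± 0.21 and Hsp27 at 1.69 ± 0.12. ER stress and ATF4 genes were higher for 7 of 24 and lower for 2 in the authors' deposited table (8 and 2 adjusted over the list alone; adjusted p = 0.572), with the stress gene Sesn at 3.22 ± 0.24, Thor at 1.31 ± 0.22 and Xbp1 at -0.73 ± 0.14. Apoptosis and DNA damage genes were higher for 6 of 22 and lower for 1 in the authors' deposited table (the same adjusted over the list alone; adjusted p = 0.330), with the cell death genes hid at 3.88 ± 0.42 and egr at 2.90 ± 0.34. RNA interference genes were lower for 4 of 14 with 0 higher (adjusted p = 0.0853), and insulin and TOR genes were higher for 2 of 19 and lower for 3 (adjusted p = 0.359) in the authors' deposited table, with the same counts adjusted over each list alone; the former passed with ranks (adjusted p = 0.0283). Housekeeping genes also changed, 3 of 11 up and 3 down in the authors' deposited table and adjusted over the list alone (adjusted p = 0.710), with Act42A at 0.68 ± 0.10, 14-3-3epsilon at -0.60 ± 0.12 and eEF2, which did not pass, at -0.08 ± 0.11.

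Fold changes rose with gene length across the genes of the authors' deposited table. Over 7088 genes with a mean of at least 10 and a symbol, Spearman's rho of the log2 fold change with the span of the gene was 0.26, and with the deposited length it was 0.15 over 7264 genes. Among the 1418 genes with the longest spans, at a median of 18410 nt, 628 were higher and 91 lower in the authors' deposited table. Among the 1420 with the shortest, at a median of 1089 nt, 122 were higher and 126 lower in the authors' deposited table. The correlation with mean expression was -0.16, and genes are not independent replicates in any of these. The authors' deposited table also marked 613 genes as changed in splicing, of which 125 were higher, 73 lower and 408 did not pass the expression test.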

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

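Counts by transcription start rows, by the authors' classes and without genes changed in splicing, and the list test with span and expression removed, were chosen after the data were seen. The count of changed genes fell from 2476 to 1064 (909 higher, 155 lower) at adjusted p under 0.0001 and 1.5-fold, and to 1019 (874 and 145) with Bonferroni. Lower genes fell to 511 at adjusted p under 0.01 and to 502 with a 1.5-fold limit, all of these by construction of a stricter limit. The authors' classes held 967 (824 and 143), all within the 1064 and with 0 marked as changed in splicing. Centring on ribosomal proteins gave 2543 higher and 198 lower genes, a shift of 0.34 in every gene. It turned Cpsf6, which had passed as lower, to 0.0069 with no call, and 11 named genes that had not passed: IntS8 to 0.20, IntS1 to 0.0014, IntS11 to 0.10, IntS14 to 0.059, asun to 0.18, Pp2A-29B to 0.12, tws to 0.14, wdb to 0.29, ATPsynbeta to 0.19, RpS6 to 0.18 and eEF2 to 0.25. The other counts stayed within 1.5 times. Over the named genes and their alternatives, IntS8 apart, 957 values kept direction and call. Much of that count was fixed in advance and is no measure of robustness. Only the centrings could change a direction, since the other alternatives reuse the deposited fold change, and a stricter limit cannot add a call. With direction kept, 75 lost the call and 7 gained it, and of the 11 that turned Cpsf6 lost it and eEF2 gained it (adjusted p = 0.0487). IntS8 did not pass under any alternative run, and the stricter limits could not have given it a call. Once span and expression were removed, 10 lists passed, 9 of the 16 called before and heat shock, and 9 kept direction and call under all 7 alternatives. The list test compares members with the other genes, so centring, which shifts all fold changes alike, tests these calls little. The cell cycle list kept its lower call on the ribosomal protein scaling, although 7 members were then higher and 5 lower. Lists that turned had no call: heat shock with ranks (adjusted p = 0.996) and housekeeping genes with random lists (adjusted p = 0.516), ribosomal centring (adjusted p = 0.641) and span removal (adjusted p = 0.405). Within quartiles of expression the correlation of fold change with expression was -0.217, -0.0208, 0.0285 and -0.0904, with deposited length 0.404, 0.212, 0.133 and 0.175, and with gene span 0.459, 0.318, 0.273 and 0.285; the cause was not tested. No paired analysis was possible because the table holds group means only. For the same reason leaving out a replicate, other splits of the samples, other count tests, pseudocounts, size factors and an estimated correlation were not run. Depth limits genes near the floor of 3 reads, where clumped reads add error that the floor does not cover.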

Other observations

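All tests and groups in this part were chosen after the data were seen. Families were formed from shared symbol stems with at least 10 tested members, and 8 of 31 passed cameraPR at adjusted p under 0.05 in the authors' deposited table. Serpins (Spn), inhibitors of serine proteases, were higher for 6 of 11 with 0 lower (adjusted p = 0.0115), with Spn88Eb going from 11.4 to 208. Nucleoporins (Nup) were lower for 9 of 21 with 0 higher (adjusted p = 0.00876), with Nup107 at a log2 fold change of -0.86 ± 0.20 (SE) and Nup50 at -0.73 ± 0.14 in the authors' deposited table. Mitochondrial ribosomal proteins (mRp) were lower for 9 of 68 with 0 higher at a median of -0.48 (adjusted p = 0.0141). Of the 7264 genes with a mean of at least 10, 877 were lower when adjusted over genes of that mean rather than by the deposited adjusted p. That share is near the mRp share, so the count of lower mRp genes does not by itself set the family apart. Translation initiation factors (eIF) were lower for 7 of 33 and higher for 2 at a median of -0.25 (adjusted p = 0.0367). The eIF median turns on the ribosomal protein scaling, with its shift of 0.34. No family was tested on that scaling, with Fisher's exact test or with span and expression removed. The other 4 families, Cyp, ND, RpL and RpS, repeat lists already described.

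Some genes with no control read in the authors' deposited table are given here as examples, with no test of whether genes of their kinds were enriched. The morphogen gene dpp was at 90.5 and at least 115-fold higher in the libraries labelled IntS8-depleted, and the homeobox genes Dll, eve and exex were at 82.7, 49.8 and 38.1. The receptor genes sNPF-R, Oamb and TyrR were at 103, 65.3 and 36.2 in that table.

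Such genes moved one way: 147 genes were at or under the floor of 3 reads in the control group and had a mean of at least 20 in the group labelled IntS8-depleted, against 1 gene the other way. Greater depth is argued against, since the mean size factor of the libraries labelled IntS8-depleted was 0.916 of that of the control libraries. Duplicated reads in 1 library are argued against too, as 99.3% of the 147 genes passed the deposited test, and of the 108 with a mean under 100, 97 had reads in all 3 libraries and 0 in 1 library alone. RNA of another cell line or cell type in the group labelled IntS8-depleted may still account for it and cannot be told apart here, because no profile of such cells is in the table, and Tig alone took 0.433% of the summed counts there. A release of silent genes by loss of IntS8 stays open, as a hypothesis not tested.

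The X chromosome stood apart: its 1017 genes with a mean of at least 100 had a median log2 fold change of 0.18, against -0.08 for 4757 autosomal genes, and 284 were higher against 41 lower. No permutation of the chromosome label over genes gave as large a difference (p = 0.0001, the smallest that 10000 permutations can give, with genes not independent). Differences in expression and span do not account for it, since within 25 cells of both the difference was 0.262 (95% resampling interval 0.194 to 0.324), nor does a gained segment, since 100% of the 12 windows of 2 Mb lay above the autosomal median, as did all 11 without the 1 that holds only 3 genes. A different count of whole X chromosomes between the cultures cannot be told apart from a response of X-linked genes, as the difference is 1.19-fold and no DNA was measured. RNA of another cell line or cell type, left open above for the silent genes, was not excluded here either. The dosage compensation RNA lncRNA:roX1 was higher, at 24981 and 41941 (log2 fold change 0.75 ± 0.17 in the authors' deposited table). This gene alone does not decide between these explanations. An effect of IntS8 loss on X-linked genes may be a candidate explanation that was not tested.

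The IntS8 row, identified by its neighbours and length only, had recovered reads that were uneven across the libraries labelled IntS8-depleted. Its group mean is met by 1 combination of whole reads, as were 100 of 100 such means of 400 to 600, though 53 of 100 means shifted off the steps found a match too. That combination has normalized values of 706, 47.2 and 705, a ratio of 14.95 between highest and lowest, while the control mean is met by 2 combinations and was not resolved. Libraries that were not depleted cannot be told apart from depleted ones: 89.8% of the 108 genes silent in control with a mean of 20 to 100 had reads in all 3 libraries, at median shares of normalized reads of 30.5%, 30.6% and 34.4% in the same order of libraries, but the source of those genes is itself open. Reads of the transfected dsRNA counted as IntS8 may account for the high values, which cannot be told apart from intact IntS8 RNA, as the table holds no positions within the gene.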
